A study of Mus musculus with 3 samples.

How the data were processed

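Single-cell RNA sequencing was carried out on bone marrow of mice, with 1 library for each of 3 genotypes. Per the labels' protocols, 8-week-old mice received 3 doses of pIpC, a synthetic double-stranded RNA that switches on the interferon-driven Mx1-Cre recombinase, at 12 mg/kg. Marrow was taken 4 weeks after the injections. Live cells that did not bind antibodies to CD3, CD11b, Gr1, B220 or Ter119 were sorted, which removes most T cells, mature myeloid cells, B cells and late erythroid cells. Cell suspensions had a viability of 90 to 91%, and droplets were made with the 10x 3' v3 chemistry, with 11 cycles of cDNA amplification and 10 of library PCR. The libraries are called here the Cre-negative control (Rit1-M90I allele without Cre), the Lztr1 knockout (floxed Lztr1 with Mx1-Cre) and Rit1-M90I (Rit1-M90I allele with Mx1-Cre). The strain label of the control is Rit1M90I/+, heterozygous for the allele, and its title also calls it wild type.

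The authors deposited raw UMI counts per gene and barcode, which are whole-number counts of distinct mRNA tags with no normalization. Per the file headers they were written by Cell Ranger 6.1.1, and per the submitters' processing notes the genome build was mm10 and Seurat 4.1.0 was among the tools. The cell calling settings and the annotation release are not given in the sources used here. The tables list 32285 genes, and the lowest barcode in each library held 500 UMIs. Near-identical genes can exchange reads in such a count, so values of Ubb, of Hspa1a and Hspa1b, of H2-Q7, of histone genes and of immunoglobulin genes are uncertain between copies.

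The files held 8476 barcodes for the control, 3014 for the Lztr1 knockout and 11573 for Rit1-M90I, and the protocol gives the input as 3 to 6700 cells, which may be a slip, so the barcodes are not set against it. Barcodes were kept at 1000 UMIs or more, 500 genes or more and at most 10% mitochondrial UMIs, which removed 11.2% of control, 19.6% of Lztr1 knockout and 15.2% of Rit1-M90I barcodes. Doublets were called with scrublet in each library and removed, 261, 75 and 445 barcodes in the same order. These were 3.47%, 3.10% and 4.53% of the barcodes that passed, where 6.02%, 1.94% and 7.85% were expected from the cell numbers. Relative to that expectation more was removed from the Lztr1 knockout, so remaining doublets may differ between libraries. The cells kept numbered 7262, 2347 and 9372, with 62218135, 27757839 and 79796327 UMIs. The median kept cell held 6855 UMIs in the control, 9926 in the Lztr1 knockout and 6596 in Rit1-M90I. The stated mean number of reads per cell is the same for all 3 libraries.

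Cells of the 3 libraries were scaled to 10000 UMIs, log-transformed and clustered together in scanpy 1.11.5 with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. Sex-linked, mitochondrial and ribosomal protein genes, Lztr1 and Rit1 were kept out of the variable genes. No batch correction was applied. The 31 clusters were named from 217 markers of 18 classes that were fixed before the data were examined. A name required a mean marker log2 fold of at least 1 over the other cells and at least 3 markers that were 2-fold higher at 20 CPM or more. It also required at least 3 of the markers among the 10 genes with the highest fold, and more of them than any other class had there. These thresholds were set after the clusters had been seen. They left 9 clusters unnamed, which keep their numbers, and gave 16 classes. Names were rebuilt here from markers, so a class is a range of cells like the named type.

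With 1 library per genotype there was no test, and no p-value or standard error was computed from cells. A class share is given with an exact Clopper-Pearson 95% interval, and a ratio of shares with a log-normal (Katz) 95% interval. For expression, UMIs were summed per library and class and divided by the class total to give CPM (UMIs of a gene scaled to a fixed class total), with exact Poisson 95% intervals. Every interval in the text covers counting error only, not the spread between mice, which these data cannot show. For expression, the intervals also leave out the spread between cells of a class. Log2 ratios are log2 of (mutant CPM + 10) over (control CPM + 10), which understates the ratio of scarce genes. Ratios without a log are plain CPM ratios with exact conditional 95% intervals.

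Genes were named by a rule fixed before the data were examined. It took Lztr1 and Rit1 first. It then took the 4 highest and 4 lowest genes of at least 50 CPM in each of the 3 classes with the most control cells among those with at least 100 cells in every library, which were the basophil and mast cell, erythroid progenitor and neutrophil progenitor classes. It added the 5 highest and 5 lowest by the median over the 6 classes of that size, among genes with 1 sign in all of them and 50 CPM in at least 3, and the 2 highest and 2 lowest members of each gene list described. Top genes of the stem and multipotent class, with 90 cells in the Lztr1 knockout, were chosen after their values were seen. There were 26 gene lists, fixed before the data were examined, with members measured at 20 CPM or more. A list is described by its median log2 ratio, an interval from 1000 Poisson draws of its UMIs, and the percentile of that median among 10000 random lists of the same size matched on expression. That percentile describes these libraries and is no test. Of 328 list medians computed over classes and mutants, the 40 described here, from 20 pairs of list and class, were picked after all medians and a first full set of alternatives had been seen. They therefore favour large values. Some genes that the rule picked, and tests of explanations that need them, are not reported here.

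The calculation was tested on simulated counts drawn from the real totals, with 200 genes changed by known folds. Draws followed the Poisson model that the intervals assume, so their coverage does not check the spread between cells. In the neutrophil progenitor sums, over 2383 genes, genes raised 2-fold came back at a median log2 of 0.93 in the simulated Lztr1 knockout comparison and 0.92 in the simulated Rit1-M90I comparison, where 0.91 was the value put in. The 95% intervals held the true ratio for 96% and 93.5% of the changed genes. In the smaller stem and multipotent sums, over 2890 genes, the medians were 0.93 and 0.92 and the intervals held the truth for 96.5% and 97% of changed genes.

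The alternatives were every deposited barcode kept, a stricter cell filter, which required 3000 UMIs, 1000 genes and at most 5% mitochondrial UMIs together and clustered the cells again, doublets kept, other Leiden resolutions, each library clustered on its own, classes from a marker score of each cell, cells thinned to 2000 UMIs, other denominators, other scalings, a pseudocount of 1 CPM, no filter on low sums, and a mean over cells in place of a sum. Every deposited barcode, other Leiden resolutions, the marker score, thinning and other denominators were applied to shares only, not to expression. Thinning left out 685 control, 92 Lztr1 knockout and 1316 Rit1-M90I cells. Shares and sums without the mixed-profile clusters, and unnamed clusters given their best class, were added after the data had been examined. The clusters called mixed-profile were 25 and 30, the unnamed ones with no marker of their best class among their top 10 genes. A mixture of lineages was measured for cluster 30 only. Scaling by the median ratio moved the centre of the genes by 0.10 on the log2 scale in the Lztr1 knockout neutrophil progenitor sum, the only sum in which it moved by that much. Gene positions are from GENCODE M21 on mm10, which placed 32158 of the 32285 genes. That release is not stated to be the one used for the counts. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2 and matplotlib 3.10.9.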

Results

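Lineage-depleted bone marrow was profiled by droplet single-cell RNA sequencing from mice of 3 genotypes, with 1 library each. RIT1 is a small GTPase related to RAS, and LZTR1 is the adaptor through which the CUL3 ubiquitin ligase marks RIT1 and some RAS proteins for breakdown. The Rit1-M90I allele carries an altered RIT1 protein, and the floxed Lztr1 allele removes LZTR1 after Cre is induced. The comparisons ask how marrow progenitors with either change differ from a Cre-negative control given the same pIpC. Both mutant libraries carry Mx1-Cre and the control does not, so an effect of Cre itself cannot be told apart from that of either change. The deposited libraries held 67541728 UMIs in the control, 30398349 in the Lztr1 knockout and 88560148 in Rit1-M90I. No value below has a replicate, so each difference is between libraries, and parentheses give 95% intervals for counting error.

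Lztr1 mRNA was lowest in the library labelled Lztr1 knockout. Over all kept cells Lztr1 (ENSMUSG00000022761, mm10 chromosome 16, 17508688 to 17526333, plus strand) was at 17.3 CPM (16.3 to 18.3) in the control, 6.27 CPM (5.37 to 7.27) in the Lztr1 knockout and 15.2 CPM (14.4 to 16.1) in Rit1-M90I. The knockout over control ratio was 0.36 (0.31 to 0.43) over all cells. By class it was 0.27 (0.18 to 0.38) in erythroid progenitors, 0.31 (0.16 to 0.56) in the monocyte lineage, 0.39 (0.22 to 0.65) in neutrophil progenitors, 0.56 (0.27 to 1.04) in basophils and mast cells, 0.62 (0.26 to 1.34) in lymphoid progenitors and 0.56 (0.24 to 1.15) in the stem and multipotent class. The stem class value rests on 9 knockout and 53 control UMIs. The deleted exons are not given in the sources used here, so 3' tags of Lztr1 may lie outside the deleted part and their level then does not check the deletion.

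Rit1 mRNA (ENSMUSG00000028057, chromosome 3, 88716838 to 88731049, plus strand) was lowest in the control. It was at 8.60 CPM (7.89 to 9.36) there, 11.8 CPM (10.6 to 13.2) in the Lztr1 knockout and 13.5 CPM (12.7 to 14.4) in Rit1-M90I. The ratio over control was 1.37 (1.19 to 1.58) in the Lztr1 knockout and 1.57 (1.42 to 1.75) in Rit1-M90I. Basophils and mast cells carried more Rit1 mRNA than the other large classes, with 21.1 CPM (16.8 to 26.1) in the control, 29.9 CPM (21.3 to 40.9) in the knockout and 33.4 CPM (28.5 to 38.9) in Rit1-M90I. The counts do not tell M90I and wild-type mRNA apart.

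**Figure D1:**
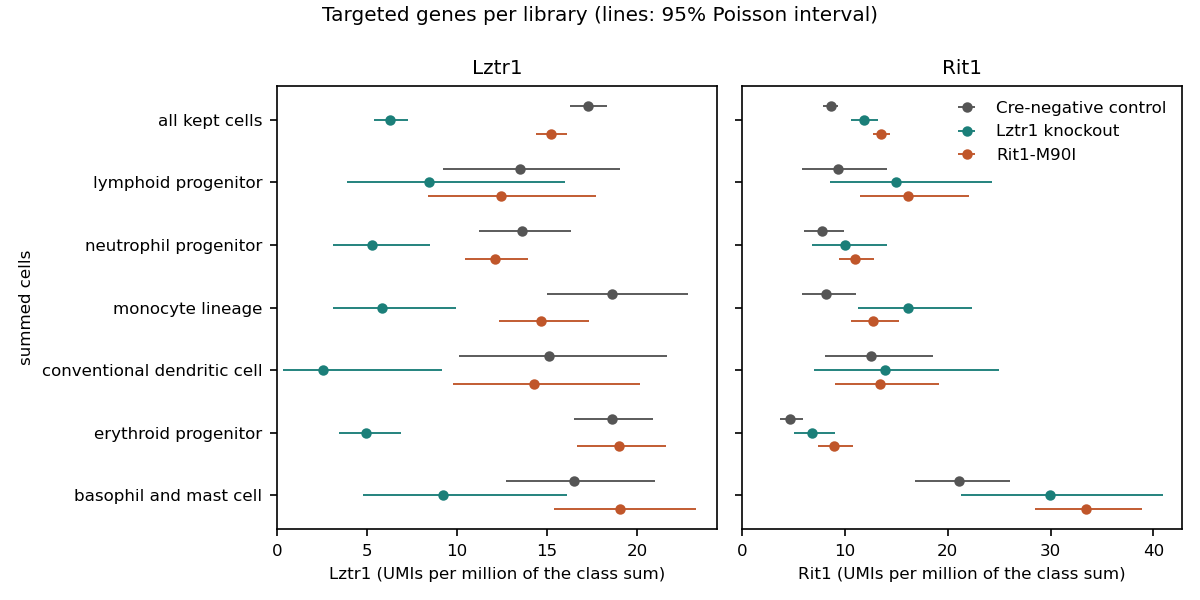
Lztr1 (left) and Rit1 (right) in CPM of the class sum (x axis) for all kept cells and named classes (y axis), with points for the 3 libraries and lines for the 95% Poisson interval. Over all kept cells Lztr1 was at 6.27 CPM in the Lztr1 knockout against 17.3 CPM in the control, and Rit1 at 8.60 CPM in the control against 11.8 and 13.5 CPM in the mutants.

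The stem and multipotent class took a smaller share of the Lztr1 knockout library than of the control, and erythroid cells took a larger share. That class was supported by 12 of its markers, among them Hlf, Mecom and Adgrl4. Others of its markers, such as Procr, Slamf1 and Ly6a, were not 2-fold higher at 20 CPM or more there. The stem and multipotent share was 3.83% (3.09 to 4.69) against 5.73% (5.20 to 6.29), a ratio of 0.67 (0.54 to 0.84). Erythroid progenitors, marked by Car1, Klf1 and Gata1, made up 13.5% (12.1 to 14.9) against 10.6% (9.93 to 11.4), and hemoglobin-rich erythroblasts 4.30% (3.52 to 5.20) against 1.18% (0.948 to 1.46). Basophils and mast cells, marked by Mcpt8, Prss34 and Cpa3, were the largest class in the control at 15.9% (15 to 16.7), against 12.9% (11.6 to 14.3) in the knockout. Share ratios whose intervals held 1 were found for neutrophil progenitors, with 8.35% (7.26 to 9.54) against 9.42% (8.76 to 10.1), the monocyte lineage, with 6.48% (5.51 to 7.55) against 6.02% (5.48 to 6.59), and lymphoid progenitors, with 5.58% (4.69 to 6.59) against 4.82% (4.34 to 5.34). When each library was clustered on its own the erythroid progenitor log2 ratio was -0.65 in place of 0.34 and that of neutrophil progenitors 0.82 in place of -0.17. The shares are those of sorted cells, and UMIs per kept cell differed between libraries.

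Cells that the lineage antibodies should have removed were present in every library. T cells were 9.75% (9.08 to 10.5) of the control, 3.03% (2.37 to 3.80) of the Lztr1 knockout and 4.61% (4.19 to 5.05) of Rit1-M90I. Their cluster was also led by Ccl5, Il2rb and Klre1, genes shared with NK cells. With the stricter cell filter, the log2 ratio of the T cell share was -0.29 in the Lztr1 knockout and 0.19 in Rit1-M90I, against -1.69 and -1.08 with the filter used. With every deposited barcode kept, that of erythroblasts in the Lztr1 knockout was 0.75 against 1.86.

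Smaller classes are given in the order control, Lztr1 knockout and Rit1-M90I. Megakaryocyte lineage cells were 3.33%, 2.47% and 2.27%, and their log2 ratios of -0.43 and -0.55 turned to 0.71 and 0.43 with each library clustered on its own. Conventional dendritic cells were 4.49%, 4.81% and 3.93%, plasmacytoid dendritic cells 0.716%, 1.24% and 0.854%, and NK cells with innate lymphoid cells 1.02%, 1.62% and 1.21%. Plasma cells were 1.75%, 1.79% and 2.26%, B lineage cells 1.31%, 0.767% and 0.491%, and stroma with endothelium 0.22%, 0.767% and 0.491%. The Rit1-M90I log2 ratio of plasma cells, 0.37, was 1.075 by marker score. That of plasmacytoid dendritic cells, 0.25, was 1.13 with each library clustered on its own. The B lineage log2 ratios of -0.77 and -1.41 were 0.045 and -0.0018 with the stricter cell filter. That of the knockout was -2.13 with each library clustered on its own, and that of Rit1-M90I -0.083 by marker score. For stroma with endothelium the knockout value of 1.80 was 5.10 with each library clustered on its own and 0.68 by marker score. By marker score the log2 ratios of conventional dendritic cells went from 0.10 and -0.19 to 0.74 and 0.25, and those of NK cells from 0.67 and 0.24 to -0.28 and -0.27. With every deposited barcode kept, the knockout value of conventional dendritic cells was 0.86. The NK cell value of Rit1-M90I was 1.27 with each library clustered on its own. Eosinophils, whose cluster was also led by the macrophage genes C1qa, C1qb and C1qc, were 0.427%, 0.298% and 0.181%, with a Rit1-M90I log2 ratio of -1.23 that was 0.39 by marker score.

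The 9 unnamed clusters, set aside by thresholds chosen after the clusters had been seen, held 23.3% (22.4 to 24.3) of control cells, 28.3% (26.5 to 30.2) of Lztr1 knockout cells and 30.3% (29.4 to 31.3) of Rit1-M90I cells. Cluster 4, led by Scin and Apoe, held 6.11%, 6.26% and 4.82% in that order, and cluster 7, with F13a1 and histone genes, 5.07%, 6.90% and 7.59%. Cluster 14, with Flt3 and Irf8, held 4.68%, 4.52% and 3.80%, cluster 18, with Tcf7 and Tox, 0.592%, 1.07% and 0.886%, and cluster 29, with Cd79a and H2-Aa, 0.468%, 0.298% and 0.800%. Cluster 25, led by Fn1 and Notch2, held 1.10% of the control, 0.0107% of Rit1-M90I and 0 of 2347 Lztr1 knockout cells, with an upper bound of 0.157%.

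**Figure D2:**
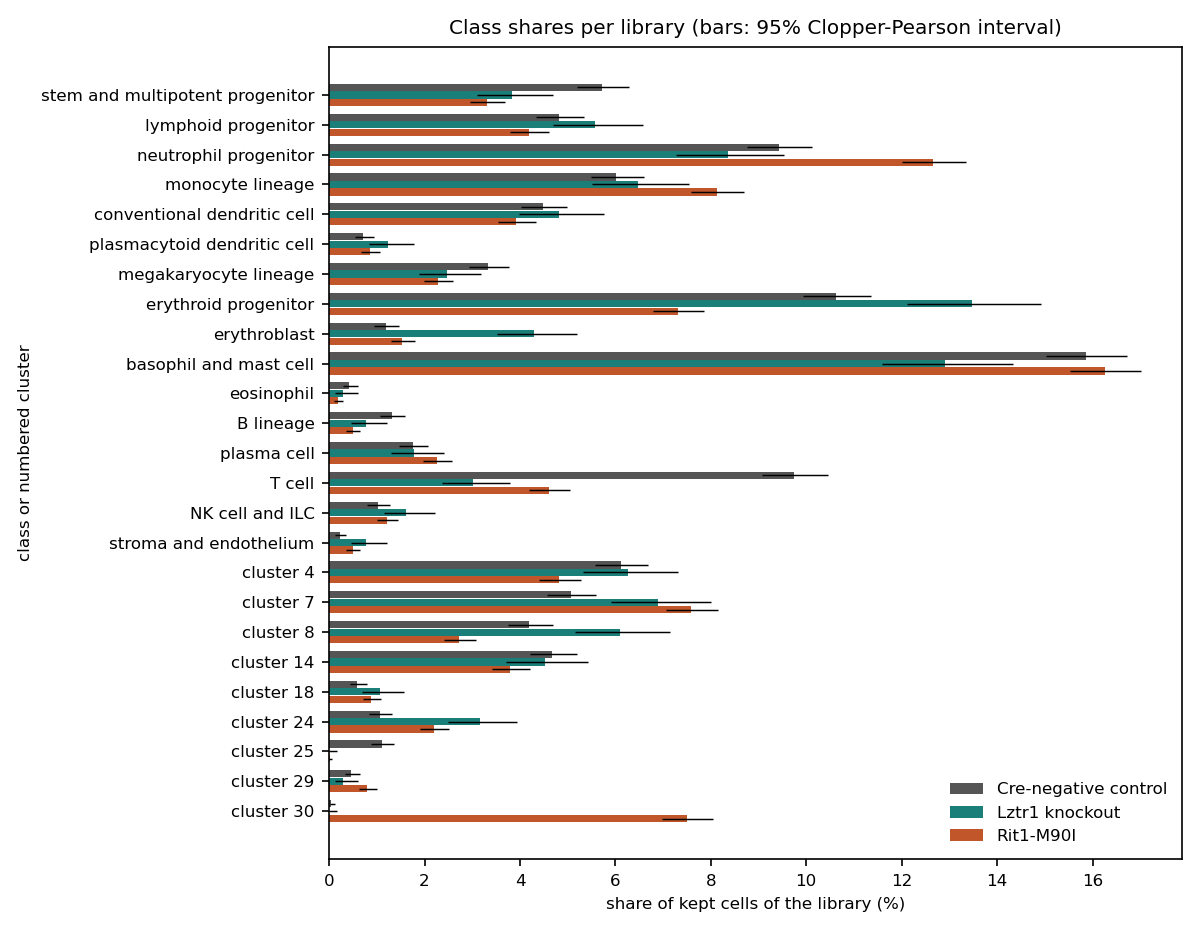
Share of kept cells of each library in percent (x axis) for each class and each unnamed cluster (y axis), with bars for the 3 libraries and lines for the 95% Clopper-Pearson interval. The stem and multipotent share was 5.73% in the control, 3.83% in the Lztr1 knockout and 3.31% in Rit1-M90I, and the erythroid progenitor share 10.6%, 13.5% and 7.31%.

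Within classes, some transcripts of the Lztr1 knockout library lay on the same side of the control in every class compared. Some of them did so in Rit1-M90I too, as given below. AA465934, a processed transcript on chromosome 11 (83291699 to 83294632), was at 89.7 CPM (86.2 to 93.3) against 2.62 CPM (2.23 to 3.05) in the control over all cells. Its log2 ratio was 2.72 in basophils and mast cells, 2.97 in erythroid progenitors, 2.58 in neutrophil progenitors and 2.88 in the stem class. Ubb, a polyubiquitin gene, was at 2196 CPM (2179 to 2214) against 1146 CPM (1137 to 1154). Its log2 ratio was 0.70 in basophils and mast cells, 1.01 in erythroid progenitors and 1.21 in neutrophil progenitors. Gm47283, placed at the end of the Y chromosome (90784738 to 90816464) that is shared with X, was at 168 CPM (163 to 173) against 68.2 CPM (66.1 to 70.3). Of Y-linked genes, no UMI of Ddx3y, Eif2s3y or Uty was read in any library, and Kdm5d had 0 in the control, 1 in the Lztr1 knockout and 4 in Rit1-M90I. Xist was at 1296 CPM in the control, 1241 CPM in the Lztr1 knockout and 1063 CPM in Rit1-M90I, as in female cells.

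Other genes were also on the same side in every class compared. Ccnd1, cyclin D1, was at 52.0 CPM (49.4 to 54.8) against 34.9 CPM (33.5 to 36.4), with a median log2 ratio of 0.67 over the 6 classes, and Hk2, hexokinase 2, at 44.7 CPM (42.2 to 47.2) against 33.4 CPM (31.9 to 34.8), with a lowest class log2 ratio of 0.0081. Cpt1a, which brings fatty acids into mitochondria, was lower at 26.9 CPM (25.1 to 28.9) against 48.1 CPM (46.4 to 49.8). Plin2, a lipid droplet coat protein, was at 35.8 CPM (33.6 to 38.1) against 52.8 CPM (51.0 to 54.7), the AP-1 factor gene Jund at 74.5 CPM (71.3 to 77.8) against 115 CPM (112 to 118), and the interferon-inducible membrane gene Ifitm1 at 164 CPM (159 to 169) against 295 CPM (291 to 299).

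Basophils and mast cells of the Lztr1 knockout had more Cuedc1, with 172 CPM (150 to 196) against 103 CPM (93.0 to 113). Prg2, the eosinophil major basic protein, was lower at 6.14 CPM (2.65 to 12.1) against 182 CPM (169 to 196). Itgam, which encodes the CD11b that the sort selects against, was at 44.5 CPM (33.8 to 57.5) against 87.0 CPM (78.0 to 96.7), and Pelo, a ribosome rescue factor, at 29.9 CPM (21.3 to 40.9) against 53 CPM (46.1 to 60.7). Erythroid progenitors had more of the lysosomal protease gene Ctsl, with 60.7 CPM (55.1 to 66.7) against 28.8 CPM (26.1 to 31.6), while Igha had a log2 ratio of -1.11, Fabp5, a fatty acid-binding protein, -0.69, and Tmsb10, an actin-binding protein, -0.46. Neutrophil progenitors had more of the basophil protease gene Prss34, with 282 CPM (264 to 301) against 20.5 CPM (17.6 to 23.8), a log2 ratio of 3.26 that was 1.57 with doublets kept. Wfdc21, a late granule gene, had a log2 ratio of -1.16, Plin2 -0.85 and Ifi27, an interferon-induced gene, -0.48. With each library clustered on its own the log2 ratios of Prss34, Prg2 and Wfdc21 were 1.85, -1.56 and -2.07, and that of Tmsb10 was -1.22. With doublets kept those of Prg2 and Igha above were -2.02 and -0.34 against -3.57 and -1.11.

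In the stem and multipotent class of the Lztr1 knockout, the median of S phase genes was above the control and that of stem cell identity genes below it. Of 37 measured S phase genes 11 were at least 1.5-fold higher and 0 at least 1.5-fold lower, with a median log2 ratio of 0.45 (0.36 to 0.52) at percentile 100. Rrm2, a subunit of the enzyme that makes deoxynucleotides, was at 64.1 CPM (48.4 to 83.3) against 24.5 CPM (19.1 to 30.9), and Uhrf1, which helps copy DNA methylation, at 125 CPM (102.5 to 151) against 59.7 CPM (51.1 to 69.3). Rfc2 and Pola1 were the lowest members with ratios of 1.0 (0.83 to 1.20) and 1.03 (0.73 to 1.44). Of 15 measured stem cell identity genes 5 were at least 1.5-fold lower and 1 higher, with a median of -0.43 (-0.61 to -0.31) at percentile 0. Pdzk1ip1 was at 16.0 CPM (8.76 to 26.9) against 33.5 CPM (27.1 to 40.8) and Ifitm1 at 385 CPM (345 to 428) against 644 CPM (615 to 674), while Ly6a, the Sca-1 gene, was at 79 CPM (61.5 to 100) against 38.3 CPM (31.5 to 46.1) and Ifitm3 had a ratio of 0.94 (0.85 to 1.05). Some of these genes, such as Pdzk1ip1 and Ly6a, also served as markers for the class.

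Ribosome biogenesis genes and other MYC targets had a median log2 ratio of 0.29 (0.20 to 0.34) in that class at percentile 99.99, with 0 of 25 members beyond 1.5-fold on the pseudocounted scale. Pa2g4 had a ratio of 1.45 (1.25 to 1.67) and Rrp12 of 1.70 (0.93 to 3.04), against 1.02 (0.73 to 1.41) for Nop16 and 1.02 (0.79 to 1.31) for Eif4e. Genes of the class chosen after their values were seen were Fbp1, a gluconeogenic enzyme, with 56.1 CPM (41.5 to 74.2) against 13.5 CPM (9.57 to 18.4), and the replication factor Pclaf, with 126 CPM (104 to 152) against 49.0 CPM (41.3 to 57.8). The lowest were Txnip, with 114 CPM (93.2 to 139) against 282 CPM (263 to 302), Elane, neutrophil elastase, with a log2 ratio of -1.15, Myl10 with -1.10 and Apoe with -1.06, which was -2.09 with the stricter cell filter. The class held 90 knockout cells and was left unnamed when the libraries were clustered on their own.

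Transcripts that report on RAS and MAPK signalling went different ways in the Lztr1 knockout. The list of MAPK output genes had a median log2 ratio of 0.49 (0.12 to 0.68) in lymphoid progenitors, at percentile 99.99, with 2 of 7 members at least 1.5-fold higher. Etv5, an ETS factor induced by ERK, was at 39.3 CPM (28.4 to 53.2) against 15.2 CPM (10.6 to 21), and Ccnd1 at 60.9 CPM (47.0 to 77.6) against 34.2 CPM (27.1 to 42.5), while Dusp5 had a ratio of 0.67 (0.40 to 1.08) and Myc of 0.82 (0.67 to 1.01). With each library clustered on its own that median was 0.07. It was 0.24 (0.00 to 0.35) in basophils and mast cells, where Dusp6, an ERK phosphatase, had a ratio of 1.44 (1.11 to 1.85), Myc of 1.39 (1.08 to 1.78), Ier3 of 0.90 (0.72 to 1.11) and Il1rl1 of 0.92 (0.76 to 1.11). In the stem class it was 0.20 (-0.05 to 0.53), with ratios of 1.88 (1.31 to 2.66) for Ccnd1, 1.56 (0.93 to 2.56) for Spred2, 0.72 (0.43 to 1.15) for Ier3 and 1.07 (0.93 to 1.24) for Myc.

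The list of immediate early genes, the first to answer growth factors and cell stress, had a lower median in the Lztr1 knockout. Over all cells 2 of 9 members were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -0.28 (-0.33 to -0.19) at percentile 0. That median was -0.10 with the stricter cell filter and -0.17 with no filter on low genes. Jun was at 50.8 CPM (48.1 to 53.5) against 84.8 CPM (82.5 to 87.1) and Klf2 at 11.4 CPM (10.2 to 12.7) against 23.0 CPM (21.8 to 24.2), while Klf4 had a ratio of 1.18 (1.09 to 1.28) and Junb of 0.97 (0.90 to 1.04). In the stem class the median was -0.54 (-0.81 to -0.29), with 4 of 8 members at least 1.5-fold lower. There Fos was at 8.01 CPM (3.22 to 16.5) against 26.9 CPM (21.3 to 33.6) and Jund at 74.4 CPM (57.4 to 94.9) against 158 CPM (144 to 173), while Btg2 had a ratio of 1.33 (0.86 to 2.0) and Junb of 1.05 (0.71 to 1.52). This list also moves with handling time before lysis, which is not given in the sources used here.

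Over all cells, the listed genes of the RAS pathway with at least 20 CPM lay within 1.5-fold of the control. Lztr1 and Rit1 are below that level and not counted here, and their values are given above. The 7 measured genes of RAS GTPases and the LZTR1 ligase had a median log2 ratio of -0.01 (-0.04 to 0.04) in the Lztr1 knockout, with Cul3 at a ratio of 1.08 (1.02 to 1.13), Rap1b at 0.94 (0.90 to 0.98) and Rala at 0.98 (0.91 to 1.07). The 16 measured cascade genes had a median of 0.03 (0.00 to 0.06), with the inhibitor Spred1 at 1.31 (1.20 to 1.42), Shoc2 at 1.12 (1.02 to 1.22), Araf at 0.96 (0.89 to 1.03) and Map2k1 at 0.98 (0.89 to 1.08). For Rit1-M90I the medians were -0.09 (-0.11 to -0.04) and -0.07 (-0.10 to -0.05). Its ratios were 1.05 (1.02 to 1.08) for Rap1a, 0.98 (0.94 to 1.01) for Cul3, 0.89 (0.85 to 0.93) for Hras, 1.06 (1.01 to 1.12) for Mapk3, 0.83 (0.77 to 0.89) for Sos1 and 0.87 (0.83 to 0.91) for Ptpn11. No measured member of either list was beyond 1.5-fold in either mutant.

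In Rit1-M90I the stem and multipotent class was also a smaller share than in the control, neutrophil progenitors were a larger share, and erythroid progenitors a smaller share. That of stem and multipotent cells was 3.31% (2.95 to 3.69) against 5.73%, a ratio of 0.58 (0.50 to 0.67). Neutrophil progenitors, marked by Mpo, Elane and Prtn3, made up 12.7% (12.0 to 13.4) against 9.42%, a ratio of 1.34 (1.23 to 1.47). The monocyte lineage made up 8.13% (7.59 to 8.70) against 6.02%, a ratio of 1.35 (1.21 to 1.51), and erythroid progenitors 7.31% (6.79 to 7.85) against 10.6%, a ratio of 0.69 (0.62 to 0.76). Basophils and mast cells were 16.3% (15.5 to 17.0), lymphoid progenitors 4.18% (3.79 to 4.61) and erythroblasts 1.53% (1.29 to 1.79), whose log2 ratio of 0.37 turned to -0.44 with each library clustered on its own. The monocyte class was left unnamed under several alternatives, and its log2 ratio of 0.43 was 0.024 when cells were classed by marker score.

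A further 7.5% (6.98 to 8.05) of Rit1-M90I cells fell in cluster 30, against 0.0413% of the control and 0 of 2347 cells of the Lztr1 knockout, with an upper bound of 0.157%. These cells were led by Gm42418, Snhg9 and Gm47283 and lacked enough markers of any single class.

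**Figure D3:**
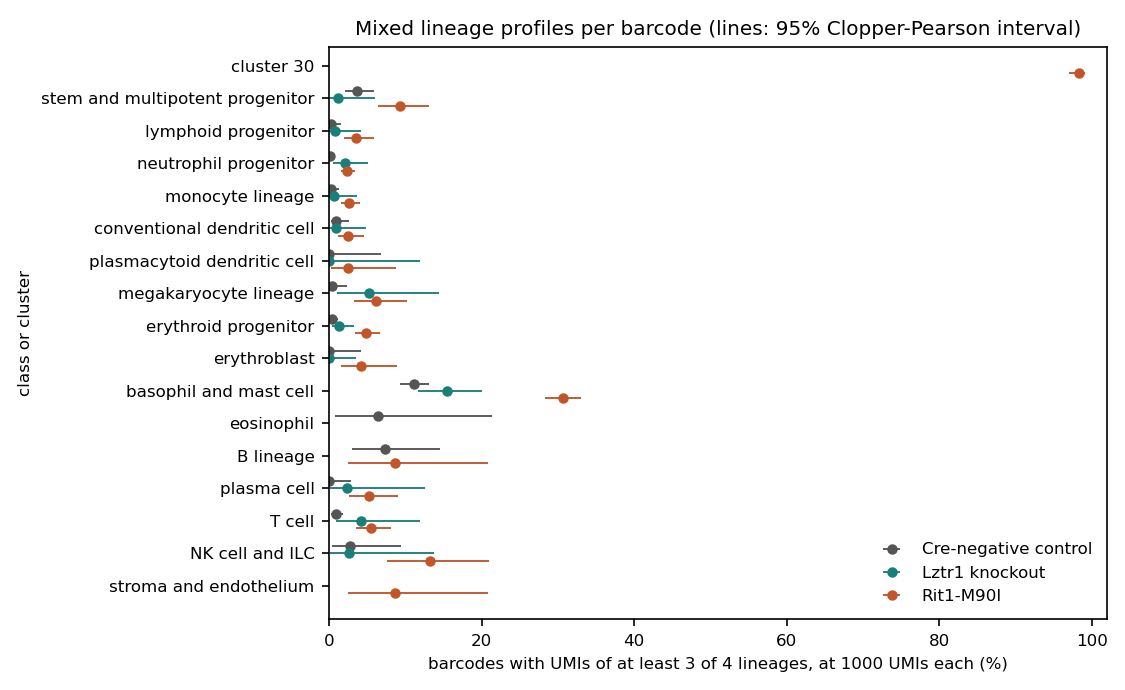
Share of barcodes in percent (x axis), each thinned to 1000 UMIs, with UMIs of at least 3 of the 4 lineages plasma cell, neutrophil, erythroid and basophil, for cluster 30 and named classes (y axis), with points per library and lines for 95% Clopper-Pearson intervals. Cluster 30 stood at 98.3% and the highest named class, basophils and mast cells, at 30.6%.

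RNA of other lineages inside classes was in part highest in the Rit1-M90I library and in part in the Lztr1 knockout. Immunoglobulin kappa mRNA (Igkc) in T cells was at 606 CPM (565 to 649) against 246 CPM (224 to 270) in the control and 302 CPM (238 to 379) in the Lztr1 knockout. Igkc in erythroid progenitors was at 134 CPM (128 to 141) against 56.2 CPM (52.5 to 60.1) and 39.3 CPM (34.9 to 44.2). Mpo, myeloperoxidase, in erythroid progenitors was at 67.1 CPM (62.6 to 71.8) against 22.9 CPM (20.6 to 25.5) and 25.9 CPM (22.3 to 29.9). Prss34 in lymphoid progenitors was at 142 CPM (127.5 to 158) against 14.8 CPM (10.3 to 20.5) and 10.3 CPM (5.14 to 18.4). The Lztr1 knockout was higher for Mpo in lymphoid progenitors, with 347 CPM (312 to 384) against 228 CPM (210 to 248) in Rit1-M90I, for Car1 there, with 160 CPM (137 to 186) against 49.3 CPM (40.8 to 59.0) in Rit1-M90I, and for Prss34 in erythroid progenitors, with 34.0 CPM (29.8 to 38.5) against 17.4 CPM (15.2 to 19.9) in Rit1-M90I. Elane in T cells was at 137 CPM (95 to 192) against 121 CPM (103 to 141) in Rit1-M90I. In basophils and mast cells of Rit1-M90I Ighg2b was at 74.7 CPM (67.3 to 82.7) against 7.61 CPM (5.13 to 10.9), with a log2 ratio of 2.27 that was 1.54 as a mean over cells, and Igkc had a log2 ratio of 1.75, the monocyte gene Ly6c2 1.27 and S100a6 1.22. Over the 6 classes of that library Igkc had a median log2 ratio of 1.36, the antibody joining chain gene Jchain 0.96 and Igha 0.74. The 6 measured primary granule genes had a median log2 ratio of 1.08 (0.96 to 1.17) in erythroid progenitors, or 0.28 with no filter on low genes, with 4 at least 1.5-fold higher, led by Prtn3 at 66.9 CPM (62.4 to 71.6) against 21.7 CPM (19.5 to 24.2) and Mpo, while Calr had a ratio of 0.87 (0.84 to 0.90) and Srgn of 1.03 (0.98 to 1.07). That median was 0.05 (-0.06 to 0.11) in the Lztr1 knockout.

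Neutrophil progenitors of Rit1-M90I carried more late granule mRNA. Of 6 measured secondary and late granule genes 4 were at least 1.5-fold higher, with a median log2 ratio of 0.80 (0.69 to 0.88) at percentile 100. S100a8, a calcium-binding protein abundant in neutrophils, was at 644 CPM (631 to 656) against 328 CPM (316 to 341) and Wfdc21 at 262 CPM (254 to 270) against 142 CPM (134 to 151). Lyz2 had a ratio of 0.82 (0.75 to 0.89) and Anxa1 of 1.12 (1.05 to 1.20). Clusters 20 and 27, both led by S100a8, held 17.4% and 30.5% of this class in Rit1-M90I against 11.5% and 28.4% in the control. With no filter on low genes the list median was 0.17, and with each library clustered on its own 0.35. For the Lztr1 knockout 1 of 5 members was lower and the median was -0.09 (-0.21 to 0.05), with Wfdc21 at 0.41 (0.35 to 0.48), Lcn2 at 0.78 (0.57 to 1.07), S100a8 at 1.03 (0.96 to 1.11) and Anxa1 at 1.11 (1.0 to 1.23). With each library clustered on its own that median was -0.79, and the S100a8 log2 ratio of 0.05 turned to -1.05. Other genes of the class in Rit1-M90I were Tfrc, the transferrin receptor, with 96.8 CPM (92.0 to 101.7) against 35.3 CPM (31.4 to 39.6), and Apoe, with 30.9 CPM (28.2 to 33.8) against 85.3 CPM (79.1 to 91.7).

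The median of mitosis genes in neutrophil progenitors was slightly above the control in both mutants, with few members beyond 1.5-fold. The G2 and M phase list had a median log2 ratio of 0.28 (0.26 to 0.35) over 39 members in the Lztr1 knockout, with 2 at least 1.5-fold higher, and 0.18 (0.15 to 0.23) over 34 members in Rit1-M90I, with 0. Both medians were at percentile 100. That of the knockout was 0.19 with median-ratio scaling and 0.48 with each library clustered on its own. In the knockout Ckap2l was at 27.1 CPM (21.7 to 33.4) against 11.4 CPM (9.27 to 14.0) and Mki67, the proliferation antigen Ki-67, at 134 CPM (122 to 147) against 85.0 CPM (78.9 to 91.5), with Cks1b at a ratio of 0.99 (0.90 to 1.09) and Tmpo at 1.12 (0.99 to 1.27). In Rit1-M90I cyclin B2 (Ccnb2) had a ratio of 1.49 (1.34 to 1.64), Cdca3 of 1.42 (1.27 to 1.60), Ctcf of 0.98 (0.90 to 1.06) and Tmpo of 0.99 (0.91 to 1.08). The S phase list in the Rit1-M90I stem class had a median of 0.08 (0.00 to 0.13), or -0.021 with the stricter cell filter, with Rrm2 at 1.44 (1.03 to 2.02), Cdc6 at 0.77 (0.55 to 1.07) and Mcm2 at 0.86 (0.72 to 1.02).

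The list of interferon response genes had a lower median in monocyte lineage cells of Rit1-M90I. The median log2 ratio over 10 members was -0.28 (-0.38 to -0.19) at percentile 0, with 1 member at least 1.5-fold lower and 0 higher, and was -0.11 with no filter on low genes. Ifi27l2a was at 32.0 CPM (28.5 to 35.8) against 73.5 CPM (66.1 to 81.5) and Trim30a at 52.6 CPM (48.1 to 57.5) against 75.9 CPM (68.4 to 84.0), while Gbp7 had a ratio of 1.24 (1.01 to 1.54) and Ly6e of 1.03 (0.99 to 1.06). In erythroid progenitors the median was -0.17 (-0.30 to -0.09), or -0.055 with no filter, with Irgm1 at 0.67 (0.58 to 0.76), Ifi35 at 0.68 (0.59 to 0.78), Ly6e at 1.06 (1.01 to 1.10) and Cmpk2 at 1.0 (0.84 to 1.17). Ifi27 was lower in every class compared, with 45.0 CPM (43.5 to 46.5) against 77.0 CPM (74.8 to 79.2) over all cells. The non-classical MHC gene H2-Q7 was lower too, with 77.9 CPM (75.9 to 79.8) against 136 CPM (134 to 139). For the Lztr1 knockout the interferon median was -0.02 (-0.13 to 0.08) in monocytes, with Irgm1 at 1.47 (1.09 to 1.98), Irf9 at 0.67 (0.48 to 0.92) and Gbp3 at 0.82 (0.64 to 1.05). The Irf9 log2 ratio of -0.42 turned to 0.044 with each library clustered on its own. The interferon median was 0.00 (-0.09 to 0.07) in erythroid progenitors, with Ly6e at 1.04 (0.99 to 1.09), Ifi35 at 0.85 (0.73 to 1.0) and Cmpk2 at 0.83 (0.67 to 1.02).

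Some early lymphoid genes gave more mRNA in the stem and multipotent class of Rit1-M90I. The lymphoid program had a median log2 ratio of 0.30 (0.20 to 0.50) at percentile 100, with 2 of 6 members at least 1.5-fold higher. The median was 0.19 with doublets kept and 0.16 with no filter on low genes. Dntt, the terminal transferase that adds bases at antigen receptor joints, was at 190 CPM (172 to 209) against 52.5 CPM (44.5 to 61.5), and Ighm at 146 CPM (130 to 163) against 74.9 CPM (65.3 to 85.5), while Notch1 had a ratio of 1.02 (0.78 to 1.33) and Satb1 of 1.18 (1.02 to 1.36). The Dntt log2 ratio of 1.68 was 0.90 with the stricter cell filter and 1.06 with doublets kept, when that of Satb1 turned from 0.22 to -0.084. The antibody genes Igkc and Jchain, which like Ighm are read in plasma cells, had log2 ratios of 1.45 and 1.05 in the class. Of its barcodes thinned to 1000 UMIs 9.36% (6.36 to 13.2) held mRNA of at least 3 of 4 lineages against 3.61% (2.03 to 5.88) in the control. For the Lztr1 knockout the median was 0.14 (-0.09 to 0.35), with Dntt at 1.64 (1.22 to 2.17), Ighm at 1.61 (1.26 to 2.04), Satb1 at 0.89 (0.72 to 1.10) and Notch1 at 0.59 (0.36 to 0.91). With doublets kept that median was -0.24, and the Dntt log2 ratio of 0.62 turned to -0.48. Genes of the Rit1-M90I class chosen after their values were seen were the chemokine gene Cxcl10, with 56.4 CPM (46.7 to 67.4) against 2.42 CPM (0.971 to 4.98) and a log2 ratio of 2.42 that was 1.29 as a mean over cells, Selp, the P-selectin gene, with 38.1 CPM (30.2 to 47.3) against 80.4 CPM (70.4 to 91.4), Myl10 with a log2 ratio of -0.91, Hk3 with -0.70 and Btbd9 with -0.66. Stem cell identity genes had a median of -0.07 (-0.20 to 0.02), or 0.042 with no filter on low genes, with Ly6a at a ratio of 1.62 (1.25 to 2.10) and Mllt3 at 1.33 (0.99 to 1.80).

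MAPK output genes of Rit1-M90I had medians whose intervals held 0 in the classes given here, and the difference between the mutants was not tested. Their median log2 ratio was 0.14 (-0.07 to 0.32) in lymphoid progenitors, with Emp1 at a ratio of 1.43 (1.07 to 1.91), Ccnd1 at 1.16 (0.86 to 1.58), Dusp6 at 0.80 (0.54 to 1.17) and Myc at 1.02 (0.88 to 1.18). With each library clustered on its own that median was -0.10, and the Ccnd1 log2 ratio of 0.17 turned to -0.93. The median was 0.08 (-0.04 to 0.22) in basophils and mast cells, with Dusp6 at 1.48 (1.24 to 1.77), Ier3 at 1.17 (1.03 to 1.34), Il1rl1 at 0.99 (0.88 to 1.12) and Spry2 at 0.79 (0.68 to 0.92), and 0.07 (-0.25 to 0.27) in the stem class, with Egr1 at 2.63 (1.65 to 4.27), Ier3 at 1.09 (0.80 to 1.48), Myc at 0.84 (0.75 to 0.95) and Dusp6 at 0.52 (0.31 to 0.86). Immediate early genes had a median of -0.06 (-0.10 to -0.01) over all cells, with Junb at 1.16 (1.10 to 1.22), Klf4 at 1.13 (1.06 to 1.20), Jun at 0.71 (0.68 to 0.74) and Jund at 0.76 (0.74 to 0.79). That median was 0.015 with the stricter cell filter. In the stem class it was 0.04 (-0.16 to 0.18), with Junb at 1.66 (1.29 to 2.13), Klf6 at 1.26 (0.85 to 1.88), Jun at 0.80 (0.68 to 0.93) and Dusp1 at 0.67 (0.42 to 1.05). Ribosome biogenesis genes there had a median of 0.01 (-0.04 to 0.07), with Wdr43 at 1.15 (1.0 to 1.34), Mybbp1a at 1.15 (0.99 to 1.33), Ppan at 0.82 (0.67 to 1.0) and Rrp9 at 0.77 (0.55 to 1.08).

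Some genes of Rit1-M90I were on the same side in every class compared. They included the non-coding RNAs Gm42031, with 46.1 CPM (44.6 to 47.6) against 4.02 CPM (3.54 to 4.55), and Gm49980, with 69.1 CPM (67.3 to 71.0) against 36.7 CPM (35.3 to 38.3). The class log2 ratios of Gm42031 ran from 0.13 to 3.47. Cpt1a was lower at 28.0 CPM (26.8 to 29.2) against 48.1 CPM (46.4 to 49.8), and Nmral1, a redox sensor, at 34.7 CPM (33.4 to 36.0) against 54.6 CPM (52.8 to 56.4). Gm47283, Hk2 and Plin2 were also on the same side in every class of Rit1-M90I, with median log2 ratios of 0.68, 0.42 and -0.40. Gm49980 was so in the Lztr1 knockout, with 0.49. These genes, like Cpt1a, are thus not particular to 1 mutant. In basophils and mast cells Prg2 had a log2 ratio of -1.98, H2-Q7 of -0.71 and Hist1h2ap of -0.63. In erythroid progenitors Tmsb4x had a log2 ratio of 0.73 and Gm26917 of -0.55. The Prg2 value was -0.94 with doublets kept and turned to 1.98 when each library was clustered on its own.

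**Figure D4:**
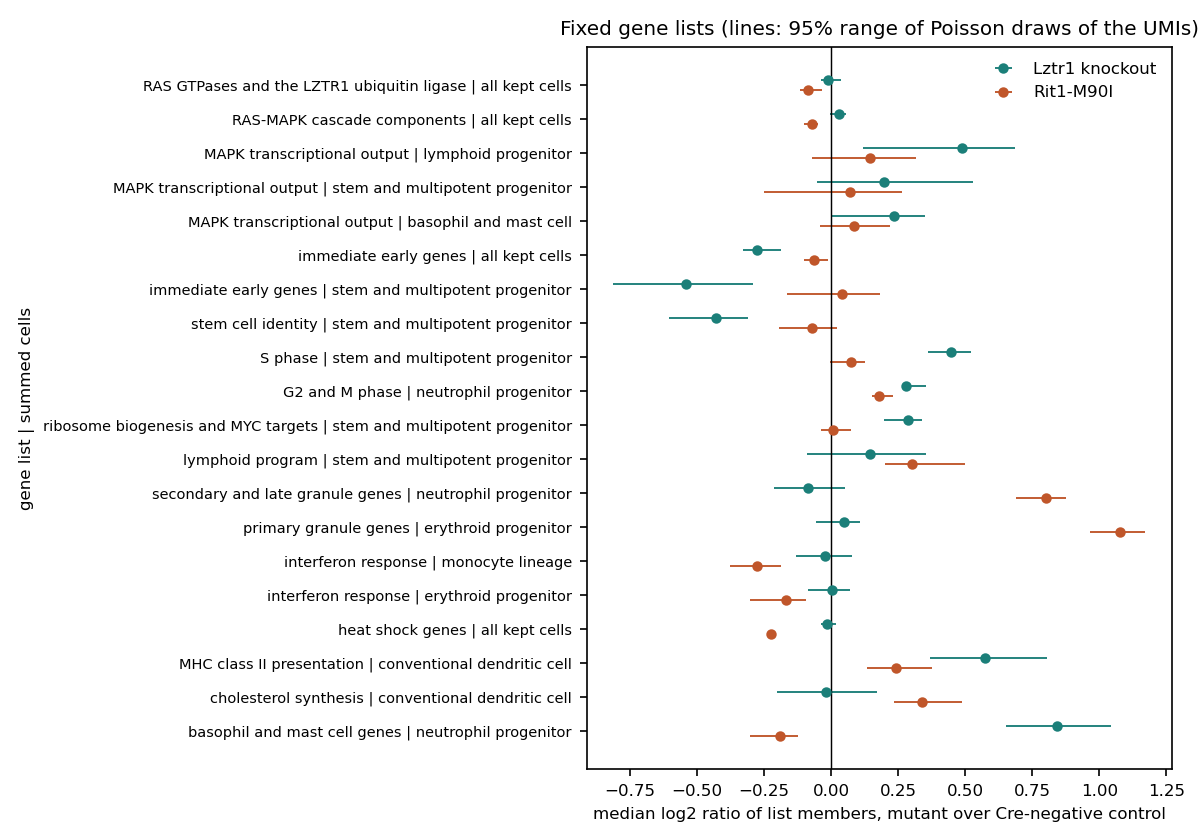
Median log2 ratio of described gene lists over the Cre-negative control (x axis) in the class they were summed over (y axis), with points for both mutants and lines for the 95% range of Poisson draws. In the stem and multipotent class S phase genes stood at 0.45 in the Lztr1 knockout and 0.08 in Rit1-M90I, and secondary and late granule genes in neutrophil progenitors at -0.09 and 0.80.

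The expression differences of both mutants from the shared control were compared across genes, which are not independent replicates. Pearson's r of the log2 ratios was 0.45 in erythroid progenitors, 0.39 in the stem class, 0.36 in basophils and mast cells and 0.29 in neutrophil progenitors, over genes of at least 50 CPM. Unchanged libraries simulated against that control gave 0.38, 0.31, 0.37 and 0.43 in the same order. The simulated libraries held counting error only, while the observed ratios also hold other spread, which enters r. An r below the simulated one therefore does not show less agreement than in unchanged libraries. Over all kept cells, where class make-up also enters, r was 0.31 against a simulated 0.41. Spearman's rho there was 0.02, and 47.5% of 2969 genes had the same sign in both mutants. The covariance over all kept cells was 0.0089 against a simulated 0.00028. The covariance was 0.0073 in erythroid progenitors against a simulated 0.0011, 0.0183 against 0.0065 in the stem class, 0.0109 against 0.0045 in basophils and mast cells and 0.0088 against 0.0021 in neutrophil progenitors. Part of the excess may come from the shared control, since its own departures enter both ratios. Its cells were not divided between the comparisons, and departures of the whole library would stay shared even then. Cre, present in both mutants and absent from the control, is a further shared difference that cannot be told apart. The direct Lztr1 knockout over Rit1-M90I log2 ratio had an SD across genes of 0.13 in erythroid progenitors, 0.25 in the stem class, 0.20 in basophils and mast cells and 0.21 in neutrophil progenitors.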

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

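The tests of free RNA, of droplets with more than 1 cell and of a single-lineage cell type in cluster 30 were all chosen after the cluster had been seen.

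With the libraries clustered together, erythroid progenitor shares lay on opposite sides of the control in the mutants, with a log2 ratio of 0.34 in the Lztr1 knockout and -0.54 in Rit1-M90I, and the difference between the mutants was not tested. With each library clustered on its own both lay below the control, at -0.65 and -0.66. Cluster 8, an unnamed cluster led by Mxd3, Kif23, Cox6a2, Runx2 and Dntt, held 4.20% of the control, 6.09% of the Lztr1 knockout and 2.72% of Rit1-M90I. Its log2 ratios of 0.54 and -0.63 were likewise not tested against each other.

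Cluster 30 held 7.5% of Rit1-M90I cells and almost none of the other libraries, and was not among the classes compared, though its cells count in the total of every share and in sums over all kept cells. Its median of 1627 UMIs lay below the library's 6596, which argues against droplets with more than 1 cell. Thinned to 1000 UMIs, 98.3% of its barcodes held mRNA of at least 3 of 4 lineages against 30.6% in basophils and mast cells, the highest named class. Without thinning these were 99.7% and 75.1%, and the highest named class was erythroblasts with 84.6%. A cell type of 1 lineage cannot be told apart, since free RNA around such cells could give such a mixture. Free RNA did not do so to that extent in B lineage barcodes of Rit1-M90I. With a median of 1604 UMIs, their thinned share was 8.70% (2.42 to 20.8). Free RNA or broken cells in droplets cannot be told apart either. Its profile correlated with that of the library's barcodes under 1000 UMIs at r = 0.965 across genes, above the 0.949 of the next cluster, but it also came first against all kept cells, at 0.988, as any mixed profile would. Genotype and handling cannot be separated with 1 library, so a biological source of these barcodes was not tested.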

How the results depend on the processing

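The settings without the mixed-profile clusters and with unnamed clusters given their best class were chosen only after the data had been seen. No paired analysis was possible because each genotype has 1 library. Of 97 alternative share ratios for the 5 main classes 83 stayed within the counting interval, as did 160 of 200 for other classes, 87 of 105 for the main list medians, 165 of 202 for other list medians and 1497 of 1752 for named genes. For named genes the interval was widened where needed to hold the main value. A pseudocount of 1 CPM cannot leave that interval, so its 257 values, all counted as within, say nothing about stability. The stem and multipotent share was lower than in the control in both mutants under every setting that named the class, from -0.78 to -0.31 in the Lztr1 knockout and from -1.03 to -0.64 in Rit1-M90I. The S phase median in the Lztr1 knockout stem class ranged from 0.38 to 0.49 under the settings run for sums. Thinned cells, other Leiden resolutions, the marker score and every deposited barcode were run for shares only. Depth was thus not tested for this median. The median cell of the class held 9844 UMIs in the knockout and 6468 in the control. The stem class had no value when each library was clustered on its own, and the monocyte class had none for either mutant at Leiden resolutions 0.5 and 2, with the stricter cell filter, with doublets kept and with thinned cells. Of the Lztr1 knockout classes described by lists, conventional dendritic cells held 789393 UMIs and the stem class, with 90 cells, 873363. With no filter on low sums the rule would keep 31 of 64 named genes, and their own values do not move. The causes of the shifts below were not tested.

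Share log2 ratios moved as follows. Clustering each library on its own gave -0.65 for erythroid progenitors in the Lztr1 knockout, 0.82 and 0.63 for neutrophil progenitors in the Lztr1 knockout and Rit1-M90I, and 0.71 and 0.43 for the megakaryocyte lineage. Thinned cells gave -0.46 and 0.64 for neutrophil progenitors and -0.088 and 0.20 for basophils and mast cells, and Leiden resolution 0.5 gave 0.61 for neutrophil progenitors in Rit1-M90I. Doublets kept gave -1.03 for the stem class in Rit1-M90I. For the monocyte lineage every deposited barcode gave -0.19 and 0.074, and in Rit1-M90I the marker score of each cell gave 0.024 and best classes 0.60. Best classes gave -0.37 for erythroid progenitors in Rit1-M90I. The stricter cell filter gave 0.19 for T cells in Rit1-M90I and 0.045 for B lineage cells in the Lztr1 knockout, and the marker score 0.39 for eosinophils in Rit1-M90I and -0.28 for NK cells in the Lztr1 knockout.

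List medians moved as well. Clustering each library on its own gave 0.070 and -0.10 for MAPK output in lymphoid progenitors, and in neutrophil progenitors 0.48 for G2 and M phase in the Lztr1 knockout and -0.79 and 0.35 for late granule genes. With no filter on low sums late granule genes were at 0.17 in Rit1-M90I, G2 and M phase at 0.25 and immediate early genes over all cells at -0.17 in the Lztr1 knockout, monocyte interferon genes at -0.11 and basophil genes in neutrophil progenitors at 0.0031 in Rit1-M90I. A pseudocount of 1 CPM gave 0.92 for late granule genes in Rit1-M90I and -0.37 for immediate early genes in the Lztr1 knockout. The stricter cell filter gave -0.10 and 0.015 for immediate early genes over all cells and -0.021 for S phase in the Rit1-M90I stem class, and the mean over cells gave -0.19 for immediate early genes in Rit1-M90I. For G2 and M phase the median ratio gave 0.19 and 0.23, and totals without abundant families 0.23 in the Lztr1 knockout. Genes of at least 200 CPM gave r of 0.46 in the stem class, 0.44 in basophils, 0.65 in erythroid progenitors and 0.37 in neutrophil progenitors, where unchanged libraries simulated against the shared control gave 0.31, 0.37, 0.37 and 0.43. These simulated values too held counting error only.

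Among named genes whose counting interval left out 0, 9 values changed sign. In Rit1-M90I Prg2 in basophils was at 1.98 with libraries clustered on their own, Hspd1 over all cells at 0.019 with median-ratio scaling and 0.10 as a mean over cells, Satb1 in the stem class at -0.084 with doublets kept, and Mvd in dendritic cells at -0.86 with the stricter filter. In the Lztr1 knockout Dntt in the stem class was at -0.48 with doublets kept, Hdc in neutrophil progenitors at -0.36 and Irf9 in monocytes at 0.044 with libraries clustered on their own, and Idi1 in dendritic cells at -0.29 with the stricter filter. Of genes whose interval held 0, these changed sign and moved by over 1.5-fold. Insig1 in Lztr1 knockout and Idi1 in Rit1-M90I dendritic cells were at -1.99 and -0.68 with the stricter filter. S100a8 in Lztr1 knockout neutrophil progenitors and Ccnd1 in Rit1-M90I lymphoid progenitors were at -1.05 and -0.93 with libraries clustered on their own.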

Other observations

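The tests of class make-up and of an unrecombined allele for Rit1, and that of class make-up for Ubb, were chosen or changed after the values had been seen.

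The median of MHC class II genes in conventional dendritic cells was above the control in both mutant libraries. For the Lztr1 knockout 4 of 8 measured members were at least 1.5-fold higher, with a median log2 ratio of 0.57 (0.37 to 0.81) at percentile 100, and it was 0.14 with the stricter cell filter and 0.36 with no filter on low genes. H2-Eb1 was at 357 CPM (317 to 401) against 138 CPM (122 to 156) and H2-Ab1 at 528 CPM (479 to 581) against 253 CPM (231 to 277), while H2-DMa had a ratio of 0.88 (0.78 to 0.99) and H2-Oa of 0.90 (0.51 to 1.53). For Rit1-M90I the median was 0.24 (0.13 to 0.38), or 0.12 with no filter on low genes, and 0 of 8 members were at least 1.5-fold higher on the pseudocounted scale, with H2-Eb1 at 1.52 (1.30 to 1.77), H2-Aa at 1.35 (1.20 to 1.52), H2-Oa at 0.95 (0.65 to 1.40) and H2-DMa at 0.97 (0.89 to 1.05). H2-Eb1 and H2-Ab1 also served to name the class, and with the stricter cell filter their knockout log2 ratios were 0.62 and 0.32 against 1.31 and 1.03. Cholesterol synthesis genes of the same class had a median of 0.34 (0.23 to 0.49) in Rit1-M90I, with Msmo1 at 2.10 (1.44 to 3.11), Mvd at 2.28 (1.41 to 3.82), Pmvk at 0.88 (0.65 to 1.19) and Idi1 at 1.17 (0.88 to 1.57). That median was -0.02 (-0.20 to 0.17) in the Lztr1 knockout, with Insig1 at 1.62 (0.93 to 2.80), Idi1 at 1.48 (1.02 to 2.12), Sqle at 0.46 (0.21 to 0.91) and Hmgcs1 at 0.72 (0.43 to 1.18). With the stricter cell filter the medians were 0.10 in Rit1-M90I and -0.52 in the knockout. With that filter the log2 ratios of Insig1 and Idi1 in the knockout turned from 0.49 and 0.47 to -1.99 and -0.29, and in Rit1-M90I those of Mvd and Idi1 from 0.78 and 0.19 to -0.86 and -0.68.

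Some basophil and mast cell genes beside Prss34 were higher in neutrophil progenitors of the Lztr1 knockout with the libraries clustered together. Of 5 measured members 4 were at least 1.5-fold higher, with a median log2 ratio of 0.84 (0.65 to 1.04), with Mcpt8 at a ratio of 2.32 (2.04 to 2.64), Ccl9 at 1.65 (1.49 to 1.82) and Hdc at 1.23 (1.08 to 1.41). With each library clustered on its own the list median was 0.39, and the log2 ratios of Mcpt8 and Hdc went from 1.09 and 0.27 to 0.038 and -0.36. With no filter on low genes the median was 0.26. In other classes of that library Prss34 was at 34.0 CPM (29.8 to 38.5) against 9.65 CPM (8.16 to 11.3) in the control for erythroid progenitors, 92.8 CPM (58.8 to 139) against 27.0 CPM (20 to 35.7) for T cells and 10.3 CPM (5.14 to 18.4) against 14.8 CPM (10.3 to 20.5) for lymphoid progenitors. In the same classes of Rit1-M90I Prss34 was at 17.4 CPM (15.2 to 19.9), 76.35 CPM (62.3 to 92.7) and 142 CPM (127.5 to 158), so Prss34 outside its lineage was not particular to the knockout. For Rit1-M90I the median was -0.19 (-0.30 to -0.12), which turned to 0.0031 with no filter on low genes, with Prss34 at 2.37 (2.01 to 2.82), a log2 ratio of 0.94 that was 0.13 with doublets kept, Ccl9 at 0.87 (0.81 to 0.95), Hdc at 0.80 (0.72 to 0.88) and Cpa3 at 0.58 (0.48 to 0.70). Heat shock genes over all cells had a median of -0.22 (-0.24 to -0.21) in Rit1-M90I, or -0.11 as a mean over cells, with the stress-induced Hspa1b at 0.33 (0.30 to 0.35), Hspa1a at 0.36 (0.33 to 0.40), Hsp90ab1 at 1.05 (1.04 to 1.05) and Hspd1 at 0.97 (0.96 to 0.98), whose log2 ratio of -0.04 was 0.019 with median-ratio scaling. That median was -0.01 (-0.04 to 0.02) in the Lztr1 knockout, with Hspa1b at 0.55 (0.50 to 0.60), Hspa1a at 0.55 (0.49 to 0.62), Hsp90aa1 at 1.14 (1.13 to 1.16) and Hsph1 at 1.12 (1.04 to 1.21). Hspa1b was also among the leading genes of cluster 25, which was almost confined to the control and counts in these sums. Cluster 24, unnamed and led by Gata3, Icos and Ccr9, was 1.06% (0.838 to 1.32) of the control, 3.15% (2.48 to 3.94) of the Lztr1 knockout and 2.20% (1.91 to 2.52) of Rit1-M90I.

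Rit1 mRNA was lower in the Cre-negative control than in both mutants. With clusters weighted as in the control the lower of the mutant ratios was 1.47 (1.27 to 1.70), which argues against class make-up. Free RNA cannot be told apart, since Rit1 in barcodes under 1000 UMIs was 2.90 times (1.06 to 6.38) its level in kept Lztr1 knockout cells, on 6 UMIs. The plan had instead set such barcodes of the mutants against those of the control. Rit1 in them was at 8.93 CPM (1.84 to 26.1) in the control, on 3 UMIs. It was at 34.3 CPM (12.6 to 74.6) in the Lztr1 knockout and 18.3 CPM (9.44 to 31.9) in Rit1-M90I, with overlapping intervals. The control is labelled heterozygous for M90I. An unrecombined Rit1 allele that gives no mRNA there would put the Lztr1 knockout, whose label names no Rit1 allele, at a ratio of 2. The observed ratio was 1.37 (1.19 to 1.58). Loss of Lztr1 could itself change Rit1 mRNA, so this explanation cannot be told apart either, a reading set after the value had been seen.

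AA465934 and Ubb were each apart in the same direction in every class of the Lztr1 knockout. The lowest log2 ratio of Ubb over the classes was 0.70, which argues against class make-up for Ubb. This is no independent test, since Ubb was picked for having 1 sign in all of those classes. For strain segments, 8 of the 30 genes farthest apart lay within 5 Mb of another, against a median of 4 and an upper bound of 10 in 10000 random draws with 1 gene per family, a step not in the planned test, so segments cannot be told apart from chance.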
